A study of Drosophila melanogaster with 9 samples.

How the data were processed

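The series holds 9 samples of whole adult Drosophila melanogaster females aged 1 to 3 days. Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map KDM5, a histone demethylase that acts on the methylated histone mark H3K4me3, and the mark itself. Per the labels' protocols, flies with an HA-tagged genomic rescue transgene of KDM5 were kept for 6 hours on 5% sucrose (control) or on 5% sucrose with 20 mM paraquat, a redox-cycling herbicide used to cause oxidative stress, and their chromatin was precipitated with an anti-HA antibody. Wildtype w1118 flies, for which no sucrose or paraquat feeding is recorded, were used with an antibody against KDM5 and with one against H3K4me3. Libraries were selected at 150 to 350 bp, per the labels' protocols. The groups were taken from the sample titles: 2 control anti-HA libraries, 2 paraquat anti-HA libraries, 1 wildtype KDM5 library, 1 wildtype H3K4me3 library and 3 inputs. The 6 ChIP libraries each had 1 deposited peak list. The inputs had no peak list and were not analysed here. Nothing in the labels says whether libraries 1 and 2 of a condition came from separate batches of flies, so the spread between them may be partly technical.

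Per the submitters' processing notes, reads came from CASAVA 1.4, Bowtie was used for alignment, peaks were called with MACS2 and the genome build was dm3. Versions and settings of Bowtie and MACS2, and the input paired with each library, are not given in the sources used here. Peaks were listed separately for each library, so no list pools replicates. The lists have no header. Their 10 columns follow the order of a MACS2 peak table, and in each row the fourth column equals end minus start, so starts count from 0. Positions are printed here counted from 1. Each deposited row holds a signal value (the pileup of ChIP fragments at the summit), the −log10 of the peak's p-value, a fold enrichment ratio over the local background, and the −log10 of the q-value, all made by the authors' peak caller. The weakest deposited peaks had a q-value of 0.0421 to 0.0498. Fold enrichments are the authors' values throughout. They were used to describe peaks, to form deciles of the wildtype KDM5 list and to recover the local background. Means and SDs of folds over anti-HA lists are descriptive, and those with n = 4 pool control and paraquat libraries.

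No list gives read totals, so the sequencing depth is unknown. The local background that MACS2 used was recovered from the deposited pileup and fold, as (pileup + 1)/fold − 1. Its lowest value in a list, which scales with reads times fragment length and was shared within 0.1% by 51.8% to 58.6% of the peaks of each anti-HA list, was 14.7 and 12.5 fragments in control libraries 1 and 2, 13.7 and 13.4 in paraquat libraries 1 and 2, 31.0 in wildtype KDM5 and 13.6 in H3K4me3. The shortest peak was 100 bp in 5 lists and 206 bp in the wildtype KDM5 list. MACS2 by default keeps no peak shorter than its fragment length, so the wildtype KDM5 list was probably called with another fragment length than the rest. Divided by the shortest peak, the background was 0.150 for wildtype KDM5 and 0.125 to 0.147 for the other lists. Pileups were whole numbers in 5 lists. In the wildtype KDM5 list all pileups were multiples of 0.892 within a tolerance of 0.02 steps, which is the form MACS2 gives when it scales a larger library down to a smaller one; no label records such a step. Widths, heights and peak numbers of the wildtype KDM5 list are therefore not on the scale of the anti-HA lists.

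Peak lists were compared by overlap of at least 1 bp. For each of the 30 ordered pairs of lists, the share of peaks overlapped was set against 1000 shuffles that moved each peak to a random place within its chromosome, between the first and last peak of any list. This one-sided permutation test can give no p below 0.001, and Benjamini-Hochberg adjustment over the 30 pairs leaves that value as it is. Peaks sit in accessible and mappable sequence, so the shuffled level is a low bar. The 4 anti-HA lists were merged with bedtools 2.31.1 into regions, and each library was scored as present or absent in each region. A region's percentile in a library is the rank of its best −log10 p within that list, where 100 is the strongest. Regions present in both libraries of one condition and in neither of the other were counted, and set beside the same counts for the other ways of splitting the 4 libraries into pairs. With 2 libraries a condition there are 3 such splits, so permuting the libraries gives no share below 1 in 3 and cannot pass 0.05. No test that assumes a distribution was run on so few libraries, and values per library are given within each replicate number as well. Intervals on shares are 95% Wilson intervals, and intervals on peaks per Mb are exact Poisson intervals. Both cover counting error only, and peaks are not replicates. Shares of peaks on chromosome 4 and the other arms were compared by Fisher's exact test, two-sided. Python 3.11.15, scipy 1.17.1, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used. Tested on simulated lists, the overlap step found 100.0% of planted overlaps among 5886 control 1 peaks, 1 of 40 draws of unrelated lists passed 0.05, and 200 of 200 planted paraquat regions were found among 2401 peaks. The planted peaks were slightly shifted copies, and the unrelated lists were placed at random and tested with fewer shuffles. These runs therefore check the code only, and give no error rate for real peaks.

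The main comparisons, the alternatives and the rule for named items were fixed before the data were examined. Among them were 25 gene lists, tests at promoters and tests of promoter motifs. These needed a gene annotation or sequence of dm3. The gene table at hand has coordinates of another assembly (Release 6), and coordinates were not converted, so no gene names, promoters or motifs were analysed here and the gene lists have no result. Peaks are named by position under the fallback rule: the 5 regions with the highest mean percentile among those in all 4 anti-HA libraries, and up to 5 in each of the paraquat and control classes. The alternatives were the upper 50% of each list by −log10 p, lists cut to the length of the shortest (4853 peaks), intervals of 200 bp around the summit, overlap of at least 50% of both intervals, summits within 250 bp, and leaving out each library in turn. Restriction to the chromosome arms, and equal list lengths together with 200 bp intervals, were added after seeing the data. Deciles of wildtype KDM5 fold and folds with and without H3K4me3 were not among the fixed comparisons. Neither were distances between KDM5 and H3K4me3 summits, nor rank correlations of peak scores.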

Results

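KDM5 binding was mapped in 4 anti-HA libraries from flies carrying HA-tagged KDM5 and in 1 library of wildtype flies made with an antibody against KDM5, and H3K4me3, a mark of active promoters, was mapped in 1 wildtype library. The control anti-HA lists held 5886 and 4919 peaks, a mean of 5402.5 ± 684 (SD, n = 2), and the paraquat lists 7403 and 4853 peaks, a mean of 6128 ± 1803 (SD, n = 2). The wildtype KDM5 list held 8948 peaks and the H3K4me3 list 7287, each from a single library with no replicate. Anti-HA peaks were narrow, with median widths of 311 ± 8.5 bp in control and 348 ± 29.7 bp in paraquat libraries (SD, n = 2 each). They covered 1.94 ± 0.187 Mb and 2.54 ± 0.849 Mb. Wildtype KDM5 peaks had a median width of 825 bp and covered 8.33 Mb, and H3K4me3 peaks had a median width of 216 bp and covered 2.06 Mb. The median fold enrichment over background, as the authors' caller gave it, was 3.05 ± 0.095 in control and 3.13 ± 0.091 in paraquat libraries (SD, n = 2 each). It was 5.47 in wildtype KDM5 and 2.40 in H3K4me3. Read totals were not given in the lists, so the depth is unknown, and the backgrounds implied by the lists are given with the processing.

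KDM5 peaks were spread over all chromosome arms. In the control anti-HA libraries the density was 49.8 ± 5.9 peaks per Mb on 2R, 45.9 ± 5.5 on 3R, 41.4 ± 2.4 on X, 40.8 ± 2.8 on 3L and 39.3 ± 1.8 on 2L (SD, n = 2). The X chromosome held 17.9% ± 0.54 of the control peaks on arms and 18.2% ± 0.20 of the paraquat peaks (SD, n = 2 each), a difference smaller than the spread between control libraries. Within numbers, control and paraquat had 17.5% and 18.05% for number 1 and 18.28% and 18.33% for number 2. Chromosome 4, the small and largely heterochromatic dot chromosome, held 31.0 peaks per Mb in control library 1 and 10.1 in control library 2, with exact Poisson intervals of 22.2 to 42.3 and 5.37 to 17.2. In paraquat libraries 1 and 2 it held 41.9 (31.5 to 54.7) and 14.7 (8.88 to 23.02). In the wildtype KDM5 list its density was 83.02 peaks per Mb (68.0 to 100.3), against 65.1 to 82.1 on the other arms. H3K4me3 density was 35.8 to 43.2 peaks per Mb on the large arms and 18.6 (11.9 to 27.7) on chromosome 4.

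The first comparison asked how far the anti-HA libraries found the same sites. Merging the 4 lists gave 7537 regions, of which 3370, or 44.7% (95% Wilson interval 43.6 to 45.8), had a peak in all 4 libraries. With the upper 50% of each list by score the number was 1737. These shared regions were wide and strong, with a median width of 687 bp and a median percentile of 66.4 within their lists. The 2457 regions found in 1 library were weak, with a median width of 141 bp and a median percentile of 16.3, and 1815 of them came from paraquat library 1. In control library 1, 85.2% of control 2 peaks had a partner, and in paraquat library 1, 93.4% of paraquat 2 peaks did. The shuffled levels were 3.06% and 4.34%, and both overlaps passed the permutation test (p = 0.001, the smallest the shuffles can give). In the reverse direction control 2 overlapped 72.0% of control 1 peaks, and paraquat 2 overlapped 59.1% of paraquat 1 peaks. With an overlap of at least 50% of both intervals, the 93.4% of paraquat 2 peaks became 55.5%, and this too passed the permutation test (p = 0.001). With summits within 250 bp it became 83.5%, against 2.79% after shuffling.

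**Figure D1:**
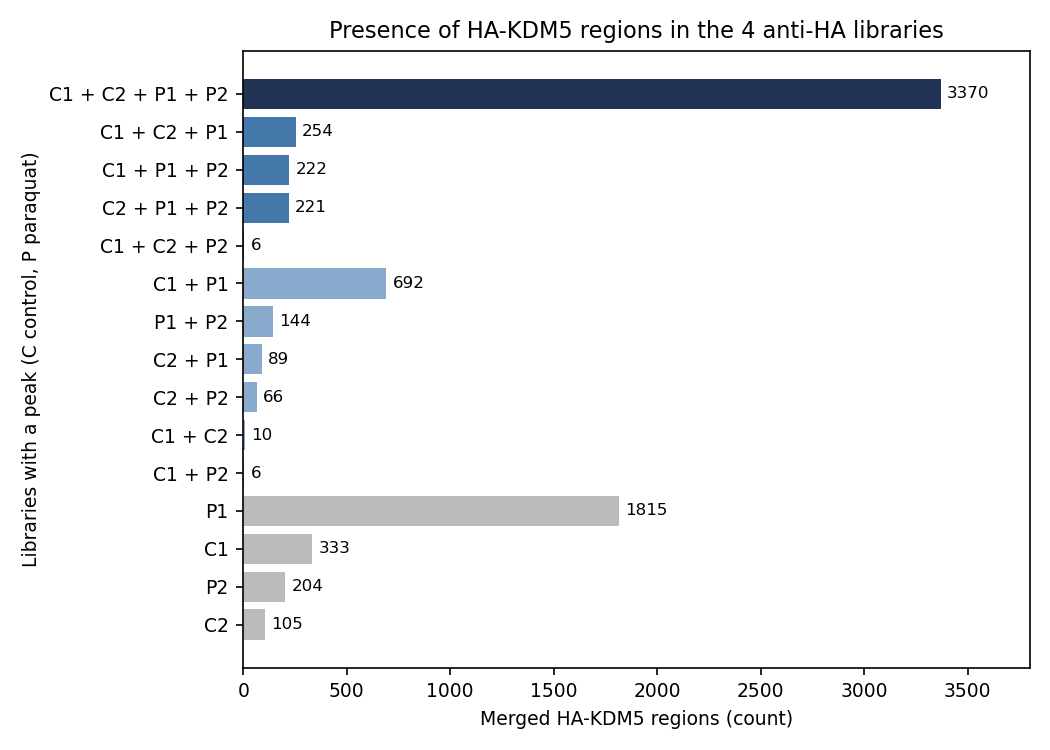
Number of merged HA-KDM5 regions (x axis, count) for each combination of the control (C1, C2) and paraquat (P1, P2) libraries that had a peak there (y axis); darker bars stand for more libraries. The 3370 regions in all 4 libraries form the longest bar, followed by 1815 regions in P1 alone and 692 in C1 and P1.

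The named regions are those with the highest mean percentile over the 4 libraries. A 755 bp region on 2R (dm3, positions 12949623 to 12950377) ranked first, with a mean fold enrichment of 9.64 ± 0.37 (SD, n = 4). It was followed by 3 regions on 3R. The one at 16152850 to 16153948 had a fold of 9.62 ± 0.44, the one at 3011460 to 3012493 a fold of 8.80 ± 0.40, and the one at 11034783 to 11035665 a fold of 8.61 ± 1.05 (SD, n = 4 each). The fifth lay on X at 12489023 to 12489726 with a fold of 8.54 ± 0.95 (SD, n = 4). All 5 also held a wildtype KDM5 peak, at folds of 9.46 to 10.5, and an H3K4me3 peak, at folds of 4.78 to 6.29. The annotation of these positions was not analysed here, because no gene models of the dm3 build were used.

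The second comparison set tagged KDM5 against the endogenous protein in wildtype flies. Of the regions in all 4 anti-HA libraries, 99.6% (99.4 to 99.8) held a wildtype KDM5 peak, against 11.3% after shuffling (permutation p = 0.001, the smallest possible). Of the 3640 regions in both control libraries the share was also 99.6% (99.3 to 99.8). The share fell to 98.2% for regions in 3 libraries, 78.4% for regions in 2 and 75.8% for regions in 1. For regions in 2 it was 70.7% of the 692 in control 1 and paraquat 1, of which 199 lay off the arms. It was 97.9% in the paraquat pair, and for control 2 it was 95.5% with paraquat 1 and 90.9% with paraquat 2. The control pair had 9 of 10, and control 1 with paraquat 2 had 5 of 6. For regions in 1 it was 46.5% in control 1, where 120 of 333 lay off the arms. It was 88.6% in control 2, 80.3% in paraquat 1 and 76.96% in paraquat 2. By library, 95.9% ± 4.2 of control peaks and 94.9% ± 4.4 of paraquat peaks overlapped a wildtype KDM5 peak (SD, n = 2 each), a difference smaller than the spread, which lies mostly between numbers. Within numbers the share was lower in paraquat both times, 91.8% against 92.9% in number 1 and 98.0% against 98.9% in number 2, and this was not tested. The reverse overlap was lower. Regions in both control libraries met 38.6% (37.6 to 39.7) of wildtype KDM5 peaks, against 4.47% after shuffling (permutation p = 0.001). With 50% of both intervals required the share was 24.8%, against 1.18% after shuffling. With summits within 250 bp it was 32.8%, against 1.44% after shuffling.

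Stronger wildtype KDM5 peaks were overlapped by anti-HA peaks more often than weaker ones. In the weakest 10% of wildtype KDM5 peaks, with folds of 1.33 to 2.04, 1.90% ± 1.95 were overlapped by an anti-HA peak (SD, n = 4 libraries). In the sixth decile, with folds of 5.47 to 6.89, the share was 57.5% ± 11.9, and in the strongest decile, with folds of 9.72 to 11.3, it was 97.2% ± 2.1 (SD, n = 4 each). These SDs pool 2 control and 2 paraquat libraries, so they are not a spread between replicates. Paraquat library 1 was highest, with 4.56% in the weakest and 75.3% in the sixth decile. The other libraries had 0.434% to 2.17% and 49.8% to 53.5%. The 3991 wildtype KDM5 peaks found in no anti-HA library had a median fold of 2.66, and the 3241 found in regions of all 4 libraries had a median fold of 8.82. The weaker wildtype peaks are also narrower, at 290 bp in the lowest decile and 1226 bp in the highest.

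**Figure D2:**
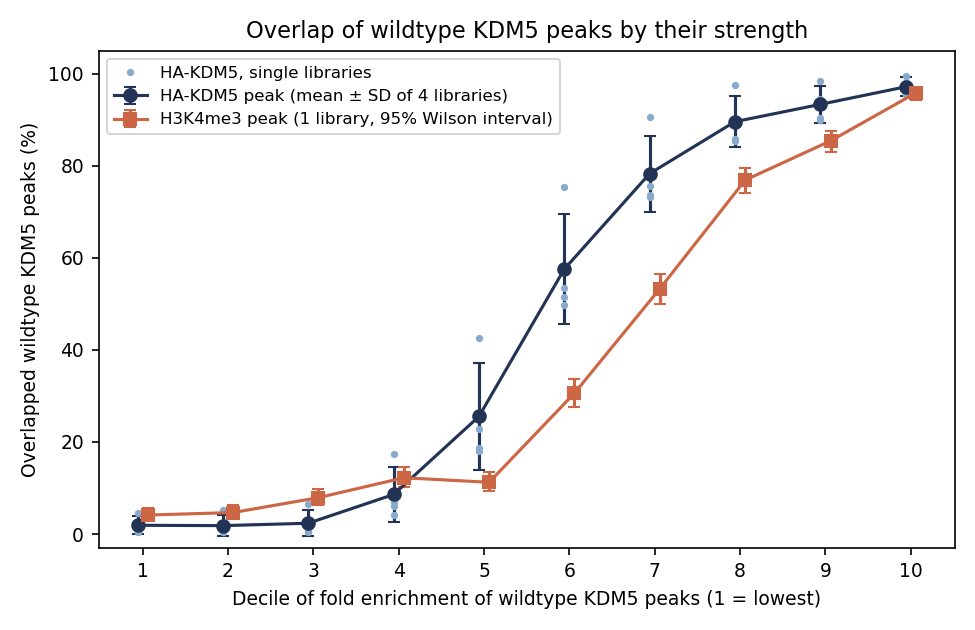
Share of wildtype KDM5 peaks (y axis, %) overlapped by an anti-HA peak (circles, mean ± SD of 4 libraries, with the single libraries as small dots) or by an H3K4me3 peak (squares, 95% Wilson interval), by decile of the wildtype peak's fold enrichment (x axis). Both shares lie below 10% in the 3 lowest deciles and reach 97.2% and 95.8% in the highest.

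The third comparison related KDM5 to H3K4me3. Of the regions in all 4 anti-HA libraries, 83.4% (82.1 to 84.6) held an H3K4me3 peak, and of those in both control libraries 80.3% (79.01 to 81.6) did. The shuffled levels were 3.81% and 3.74% (permutation p = 0.001 for both, the smallest possible). With 50% of both intervals required, the 80.3% became 38.8%, against 0.686% after shuffling. H3K4me3 peaks had a median width of 216 bp and regions of all 4 libraries 687 bp, which limits overlaps of that kind. With summits within 250 bp the 80.3% became 69.8%, against 1.92% after shuffling. By overlap of at least 1 bp, the share was 39.0% (35.4 to 42.6) for regions in 3 libraries, 27.6% (24.9 to 30.4) for regions in 2 and 12.3% (11.1 to 13.6) for regions in 1. Median widths fell in the same order, from 687 bp for regions in 4 libraries to 399, 283 and 141 bp. These shares were not matched for width, and those for 3, 2 and 1 libraries were not set against shuffles. Among the anti-HA lists 66.5% ± 2.6 of control peaks and 58.9% ± 10.5 of paraquat peaks overlapped H3K4me3 (SD, n = 2 each), a difference smaller than the spread between the paraquat libraries. Within numbers the share was again lower in paraquat, 51.5% against 64.7% in number 1 and 66.4% against 68.3% in number 2, and this was not tested. In number 1 the peaks with H3K4me3 were 3807 in control and 3812 in paraquat, and those without were 2079 and 3591. In number 2 the peaks with it were 3360 and 3220, and those without were 1559 and 1633. The mark was mapped only in wildtype flies, with no paraquat recorded. On the chromosome arms 88.3% (87.4 to 89.2) of the 4636 H3K4me3 peaks overlapped a wildtype KDM5 peak, and 73.3% (72.0 to 74.5) lay in a region of all 4 anti-HA libraries. For these shares the shuffled levels were 8.93% and 3.06%.

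KDM5 peaks with H3K4me3 had higher median folds than those without in all 5 KDM5 lists. In control libraries the median fold was 3.40 ± 0.01 with H3K4me3 and 2.58 ± 0.13 without (SD, n = 2 each). In wildtype KDM5 the medians were 8.75 and 3.27. Among wildtype KDM5 peaks 38.2% (37.2 to 39.2) overlapped H3K4me3, from 4.12% (3.02 to 5.61) in the weakest decile to 95.8% (94.3 to 97.0) in the strongest. Of the wildtype KDM5 peaks found in no anti-HA library 5.34% (4.68 to 6.08) held H3K4me3, and of those in regions of all 4 libraries 84.4% (83.1 to 85.6) did.

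Distances between summits differed with the direction in which they were taken. On the arms the median distance from an H3K4me3 summit to the nearest wildtype KDM5 summit was 121 bp, with an interquartile range of 49 to 505 bp. From control anti-HA summits to the nearest H3K4me3 summit it was 148 and 153 bp, and from paraquat summits 278.5 and 172 bp. From wildtype KDM5 summits it was 1895 bp, with 24.2% (23.3 to 25.2) within 100 bp and 43.0% (41.95 to 44.05) within 1000 bp. Within 100 bp of an H3K4me3 summit lay 39.95% (38.7 to 41.3) of the summits of control library 1 and 38.5% (37.1 to 39.9) of those of control library 2. H3K4me3 summits within 1000 bp lay on both sides of 19.8% and 23.0% of the control summits, and on one side of 61.2% and 59.8%.

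**Figure D3:**
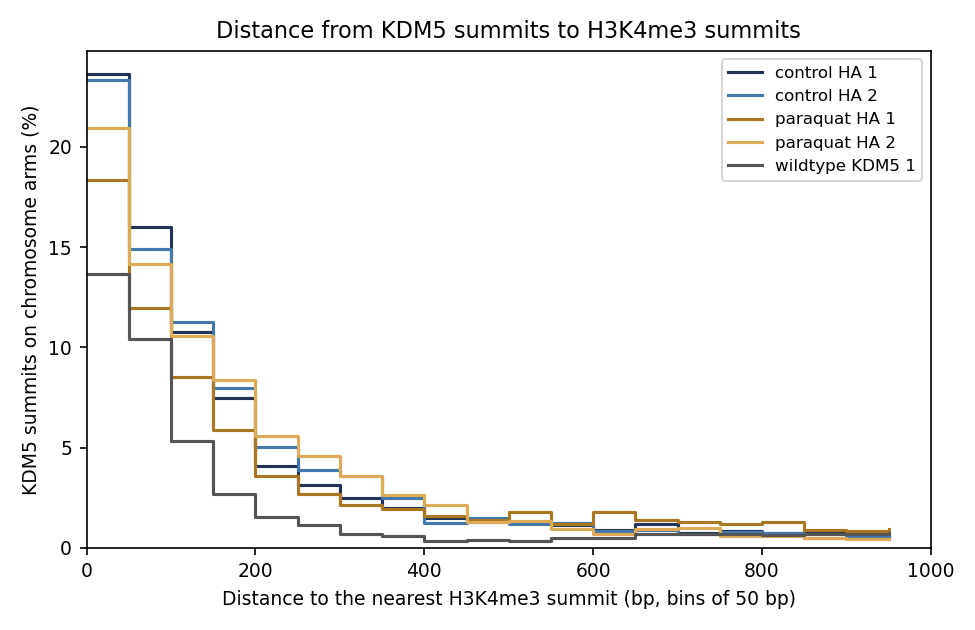
Share of KDM5 summits on chromosome arms (y axis, %) by distance to the nearest H3K4me3 summit (x axis, bp, bins of 50 bp), 1 line per library. All 5 lines are highest in the first bin and fall from there to 200 bp; summits farther than 1000 bp are not drawn.

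Wildtype KDM5 peaks on chromosome 4 were overlapped less often than those on the other arms, a comparison made after seeing the data. Of its 107 wildtype KDM5 peaks, 5, or 4.67% (2.01 to 10.5), lay in regions of all 4 anti-HA libraries, against 38.2% (37.1 to 39.2) of the 8440 peaks on the other arms (Fisher's exact test over peaks, adjusted p = 2.56e-15 over 3 comparisons). H3K4me3 overlapped 13.1% (7.96 to 20.8) of them, against 37.7% (36.6 to 38.7) elsewhere (Fisher's exact test, adjusted p = 4.13e-08). A peak in any anti-HA library was found at 39.3% (30.5 to 48.7), against 56.5% (55.4 to 57.5) elsewhere (Fisher's exact test, adjusted p = 0.000391). At the shares seen on other arms in the same deciles of fold, 42.6 of the 107 peaks would have a peak in any anti-HA library, and 42 had one, so that difference was not seen among peaks of like fold. For H3K4me3 19.2 would be overlapped and 14 were, a difference within the interval, and for regions of all 4 anti-HA libraries 20.6 would be and 5 were. The number 2 libraries held few peaks on chromosome 4, 13 in control and 19 in paraquat, against 40 and 54 in number 1, which limits how many regions of all 4 libraries it can hold. The median fold of wildtype KDM5 peaks was 3.97 on chromosome 4 and 5.40 to 6.20 on the other arms. These tests compare peaks on chromosome 4 with peaks on the other arms within the wildtype KDM5 list, which is 1 library. Peaks are not replicates, so the tests do not cover variation between libraries or flies.

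The last comparison asked whether paraquat changed where KDM5 was found. Beside the 3370 regions of all 4 libraries, 144 regions had a peak in both paraquat and neither control library, and 10 had one in both control and neither paraquat library. The 144 paraquat regions were weak, with median percentiles of 29.9 and 22.6 in paraquat libraries 1 and 2, against 75.2 and 63.9 for the regions of all 4 libraries. Of the 144, 97.9% (94.1 to 99.3) held a KDM5 peak in wildtype flies and 16.0% (10.9 to 22.8) an H3K4me3 peak. The control count rose to 35 at equal list lengths and to 108 with intervals of 200 bp, where the paraquat counts were 96 and 180. With both changes together, a setting chosen after seeing the data, the counts were 126 on the paraquat side and 121 on the control side, so the excess was no longer seen. Intervals of 200 bp can split 1 site into separate regions where summits lie apart. Some regions counted in that setting may therefore still lie in a peak of the other condition.

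The strongest of the 144 regions lay on the unplaced scaffold set Uextra at 9037112 to 9037324, with a fold of 5.03 ± 1.26 and no wildtype KDM5 peak (SD, n = 2). The next were on 2L at 16287406 to 16287964 (fold 3.28 ± 0.09), on chromosome 4 at 691745 to 692140 (3.25 ± 0.28), on X at 3614126 to 3614528 (3.25 ± 0.56) and on 2R at 13294378 to 13294921 (3.30 ± 0.33; SD, n = 2 each). These 4 held wildtype KDM5 peaks at folds of 5.64 to 9.24. Of the 10 control regions the strongest were on 2R at 19634136 to 19634296 (fold 2.90 ± 0.31), on 2L at 10436041 to 10436357 (2.66 ± 0.43), on X at 173406 to 173578 (2.55 ± 0.18) and 3467423 to 3467564 (2.47 ± 0.03), and on the unplaced scaffold U at 9170080 to 9170232 (1.91 ± 0.55; SD, n = 2 each). The 4 of these on arms held wildtype KDM5 peaks at folds of 6.04 to 8.18. The 10 control regions were weak as well, with median percentiles of 11.1 and 16.9 in control libraries 1 and 2. The region on U had a percentile of 0.05 in control library 1.

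More regions parted the libraries by replicate number than by treatment. Control 1 and paraquat 1 shared 692 regions absent from both number 2 libraries, and control 2 and paraquat 2 shared 66 absent from both number 1 libraries, 758 in all. The paraquat split gave 154 regions in all, and the remaining split, control 2 with paraquat 1 against control 1 with paraquat 2, gave 89 and 6, 95 in all. Across the 3370 shared regions the rank correlation of peak scores was 0.81 between control 1 and paraquat 1 and 0.80 between control 2 and paraquat 2, but 0.68 between the control libraries and 0.68 between the paraquat libraries (Spearman's rho across regions, which are not independent replicates). Within number 1, 2269 regions were in paraquat and not control and 355 the reverse. Within number 2 the counts were 576 and 458. Without paraquat library 1, 444 regions were in paraquat and neither control, and 287 in both controls and not paraquat. Without paraquat library 2 these counts were 1997 and 18, without control library 1 they were 371 and 118, and without control library 2 they were 383 and 346. With 3 splits in all, permuting the libraries gives no share below 1 in 3, so these counts carry no test of paraquat against control.

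**Figure D4:**
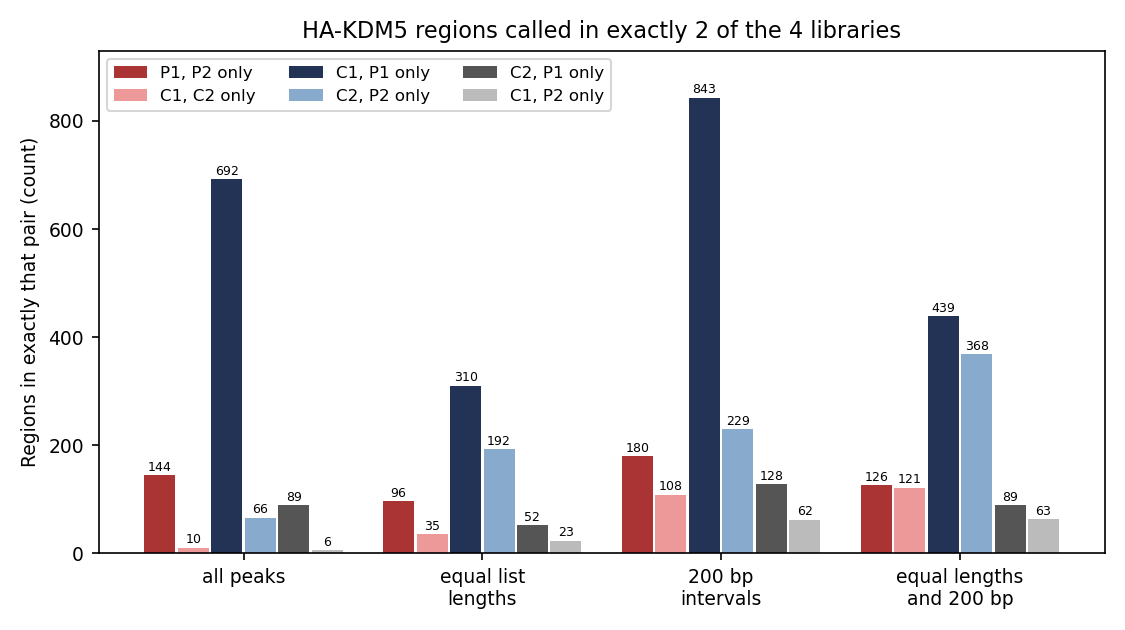
Number of HA-KDM5 regions called in exactly 2 of the 4 libraries (y axis, count) for each pair of libraries (colours; C control, P paraquat) under 4 ways of preparing the lists (x axis). The pair C1 and P1 is highest in each of the 4 settings, and the pairs of 1 condition become nearly equal, 126 and 121, with equal list lengths and 200 bp intervals.

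Peaks outside the chromosome arms were unevenly distributed. On the unplaced and heterochromatic scaffolds lay 6.24% (5.65 to 6.88) of the peaks of control 1 and 5.93% (5.41 to 6.49) of those of paraquat 1, but 1.04% (0.79 to 1.36) of control 2 and 1.07% (0.818 to 1.402) of paraquat 2. In the H3K4me3 list 36.4% (35.3 to 37.5) of the peaks lay off the arms, 2466 of them on Uextra. Of these off-arm H3K4me3 peaks 9.51% (8.45 to 10.7) overlapped a wildtype KDM5 peak and 0.49% (0.29 to 0.84) a region of all 4 anti-HA libraries. The shuffled levels were 0.68% and 0.043%, so both shares were low but above them.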

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

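Of the tests in this part, those of list length were fixed before their results were seen, and those of interval width combined with list length, of the implied background, of the scaffolds and of the pileup ceiling were chosen only after the results were seen.

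The number of peaks moved in opposite directions in the libraries labelled 1 and 2: paraquat minus control was 1517 peaks for number 1 and −66 for number 2. The difference was not tested, since each number has 1 library a condition.

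The first pattern weighed is the 144 regions in both paraquat and neither control library, against 10 the other way. With each list cut to 4853 peaks the counts were 96 and 35, a ratio of 2.74 with an exact binomial interval of 1.84 to 4.16 (counting error only), so list length alone was not the whole of it, but the side holding paraquat library 1 was also larger in the number split (310 and 192) and in the crossed split (52 and 23), so the remaining excess was not particular to treatment. With intervals of 200 bp as well, the ratio was 1.04 (0.80 to 1.35), so the excess was not seen in that setting. Such intervals can also split 1 site into separate regions where the summits of the libraries lie apart. With 200 bp intervals alone, the control count rose from 10 to 108 and regions of all 4 libraries fell from 3370 to 3061. The ratio therefore cannot tell whether longer lists and wider peaks together give the excess. Deeper sequencing of the paraquat libraries was not seen in the implied backgrounds. Both paraquat values (13.7 and 13.4) lay between those of the control libraries (14.7 and 12.5), with a ratio of means of 0.997. Within number 1 the paraquat library had the lower background and the longer list, and within number 2 the higher background and the shorter list. Read totals are unknown and each condition has 2 libraries, so deeper sequencing stays open. A change of binding with paraquat stays open and untested: under the setting with both changes the paraquat split gave 247 regions in all, the number split 807 and the crossed split 152.

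The second pattern is the sharing of regions by the number 1 libraries, 692 with all peaks. Peaks on unplaced and heterochromatic scaffolds were 28.8% (25.5 to 32.2) of the 692, so they are not the whole of it, and 493 remained on the arms. Longer lists did not bring the count down to that of the paraquat pair: at equal list lengths 310 regions were still shared by the number 1 libraries alone, against 96 for the paraquat pair. The number 2 pair rose from 66 to 192 at equal lengths, and with 200 bp intervals as well the counts were 439 for number 1 and 368 for number 2. With 200 bp intervals alone they were 843 and 229. Most of the excess of number 1 over number 2 thus went with list length, and 200 bp intervals alone did little to lower it. A shared day, batch of chromatin or library preparation is a possible explanation that no label records, and a biological difference between the flies of the 2 numbers was not tested.

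The third pattern is the crowding of wildtype KDM5 peak heights near their maximum. In that list 35.1% of peaks reached within 25% of the highest pileup, against 0.08% to 0.53% of peaks in the other lists. If a caller keeps 1 read per position and strand, no pileup can pass 2 times the fragment length. Taking the shortest peak of 206 bp as the fragment length, the ceiling is 412 fragments, and the highest unscaled pileup was 405, or 98.3% of it; the other 5 lists, with a ceiling of 200, reached 137 to 186. The data are consistent with such a ceiling, and folds of the strongest wildtype KDM5 peaks may then understate their enrichment. That strong sites in whole animals truly have like occupancy was not tested.

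In the H3K4me3 list 2466 peaks, 33.8% (32.8 to 34.9) of the list, lay on Uextra, which is outside the comparisons on chromosome arms, against 25 to 329 in the anti-HA lists and 322 in wildtype KDM5. The median H3K4me3 fold was 2.20 off the arms and 2.53 on them.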

How the results depend on the processing

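All 18 alternatives run on the overlaps (between replicate libraries, between KDM5 lists, and between KDM5 and H3K4me3) stayed above the shuffled level at a permutation p of 0.001. Requiring 50% of both intervals lowered the H3K4me3 share of control regions from 80.3% to 38.8%, and with summits within 250 bp it was 69.8%. The upper 50% of each list by score gave 1737 regions in all 4 anti-HA libraries, in place of 3370, as fewer peaks enter, and a share of control arm peaks on X of 19.1% in place of 17.9%; the cause of the latter was not tested. The 10 control regions became 35 at equal list lengths, 108 with 200 bp intervals and 121 with both; the 144 paraquat regions ranged from 96 to 180 over the settings that keep all 4 libraries. Leaving out 1 library in turn gave 371 to 1997 paraquat regions, with 371 without control 1, 383 without control 2, 444 without paraquat 1 and 1997 without paraquat 2. For control regions it gave 18 to 346, with 118, 346, 287 and 18 in the same order. These counts rise by construction, because 1 library fewer must have the peak or must lack it. Regions in all remaining libraries numbered 3393 to 3753. Counted within each replicate number (replicate block) and averaged, 1422.5 regions were in paraquat and not control and 406.5 the reverse; the blocked count needs 1 library a condition, so it is larger by construction. The labels do not say what the numbers share; deviations of the 2 numbers correlated at 0.21 across regions, as a hint from the data. Tests on genes, gene lists, promoters and motifs were not run, for want of dm3 gene models and sequence. Without read totals, absence of a peak cannot be told from a site below the threshold.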

Other observations

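The tests in this part were chosen after seeing the data. A small set of sites was strong with anti-HA and not listed for wildtype KDM5. Of the 3370 regions in all 4 anti-HA libraries, 12 had no wildtype KDM5 peak. Their median percentile was 97.4, and 10 of the 12 had a mean percentile of at least 90. Outside the arms lay 11 of them, 9 on Uextra, and 0 of the 12 held an H3K4me3 peak. Those named here were chosen after their values were seen. The strongest were on Uextra at 17026051 to 17026249, with a fold of 8.69 ± 1.34, and at 7039378 to 7039739, with a fold of 8.11 ± 1.62 (SD, n = 4 each). The one on an arm, on X at 17317653 to 17317856, was weak, with a fold of 2.75 ± 0.42 (SD, n = 4). Genotype, antibody, fragment length and recorded feeding all differ between the anti-HA and wildtype lists, so these values name no source.

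In deciles 5 to 10 of wildtype KDM5 fold, peaks in regions of all 4 anti-HA libraries held H3K4me3 more often than the other peaks of that decile, with intervals that did not overlap. In decile 4 the shares were 22.7% (10.1 to 43.4) of 22 peaks and 12.0% (9.99 to 14.3) of 886, with overlapping intervals, and lower deciles were not compared. In the sixth decile of wildtype fold, 60.1% (54.6 to 65.4) of the 311 peaks in regions of all 4 anti-HA libraries held H3K4me3, against 14.9% (12.2 to 18.0) of the 584 others. In the eighth decile the shares were 88.8% (86.2 to 90.9) and 40.5% (34.2 to 47.1), and in the highest 98.2% (97.0 to 98.9) and 62.7% (50.0 to 73.9). Heights of 35.1% of the wildtype KDM5 peaks lay within 25% of the highest, so folds crowd at the upper end, and the upper deciles do not fully match peaks for strength.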
